A study of Arabidopsis thaliana with 30 samples.

How the data were processed

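The values are raw counts per gene, per the file headers and the whole numbers they hold, in 2 deposited tables of 32833 genes each. The submitters' notes name fastp 0.23.1 for read trimming and STAR 2.7.9a for alignment to the TAIR10 build. The counting tool, the strand setting and the annotation version are not given in the sources used here. Of the IDs, 32548 were found in the gene table of reference release TAIR10.1, and 285 were not. Symbols come from that table, and no coordinates are given because the build named by the submitters and the reference release differ. The strand of the libraries is not known, so values of genes that overlap others on the opposite strand are uncertain. The same holds for close paralogs that share reads, among them CBF1 and CBF2, the LHCB1 and RBCS genes, the HSP17.6 genes, the 2S albumins, the AOC genes and many ribosomal protein genes.

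Each table was fitted on its own in edgeR 4.0.16 under R 4.3.3. Genes were kept with filterByExpr, which left 20666 genes in the bak set and 20385 in the tcp set. Library sizes were scaled with TMM, and quasi-likelihood models with robust dispersion estimates were fitted to the groups. Fold changes are log2 values from that fit. Their SE was derived as the absolute fold change over the square root of the quasi-likelihood F statistic. It is approximate, most of all for genes with few counts. Levels are given in CPM, the usual scaled count of a gene relative to its library's total, and log2 CPM uses a prior count of 2. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the 28 lists of a comparison. DESeq2 1.42.0 served as the other tool, and data.table version 1.17.8 handled the tables.

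The method was first tried on simulated counts drawn from the means, dispersions and library sizes of each set. In 1 group of 3 libraries 100 genes were changed 2-fold and 100 genes 1.5-fold, among genes with a mean of at least 1 CPM. All groups otherwise shared the same means, without an effect of submergence or genotype. Recovery may therefore differ where many genes change. A comparison of 2 groups recovered 73 of the 2-fold changes in the bak set, 83 with tcp21 and 90 with tcpq. An interaction recovered 43, 65 and 71. Of the 1.5-fold changes, an interaction recovered 7, 20 and 34. False calls made up 8.46% of the calls between 2 groups in the bak set with edgeR and 19.1% with DESeq2.

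Replicate numbers were not treated as pairs. The residual correlation between libraries of the same number in different groups lay between -0.093 and 0.071, inside the limit of 0.1 for adding a block term for pairing, so the block served only as an alternative. Whether the replicates are separate cultures is not stated, so p-values measure the spread between these samples.

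The comparisons, the tests, 28 gene lists, 27 of them with their members, and the main alternatives were chosen before the data were examined. The lists cover core hypoxia genes, group VII ERF factors, ethylene, cytosolic glycolysis, energy starvation, autophagy, senescence, abscisic acid, jasmonate, salicylic acid defence, pattern-triggered immunity, SERK receptor kinases with brassinosteroid signalling, brassinosteroid synthesis, brassinosteroid-induced genes, auxin-induced genes, class I TCP factors, circadian clock, cell cycle, photosynthesis, flavonoids, glucosinolates, heat shock, ER folding, reactive oxygen, cytosolic ribosomal proteins, root markers, stomatal lineage markers and seed storage markers. The ribosomal list was filled by a rule on product names in the annotation of the reference release. Lists of touch and wound genes and of iron deficiency genes were added after the data had been seen.

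Genes are named by a rule. BAK1, BKK1 and TCP21 are given throughout. Each comparison adds genes from its 6 largest rises and 6 largest falls among called nuclear genes that reach a mean of 5 CPM in the higher group and, between 2 groups, show no overlap of libraries. Each list described adds called members with the smallest adjusted p, and uncalled members where the text needs them. Where a group holds 10 counts or fewer for a gene, CPM of both groups are given in place of a fold change, because such a fold depends on the prior count. The fitted interaction values listed among the flagged results are an exception. Names of lists refer to their genes and not to measured hormones or processes.

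For a score of the submergence response, the genes called in Col of the other set served as the reference, so the score measures movement along that response and not the number or size of all changes. A library's score was its mean log2 CPM over the rising genes minus that over the falling genes. Mutant and Col responses were compared by a two-sided exact permutation test that exchanged genotype labels within each treatment, with 400 arrangements and a smallest p of 0.005. The effect of a Col group shared by 2 comparisons was simulated in 20 draws of unchanged mutant groups. No call rests on an order of replicates.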

Results

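The data are gene counts from poly-A RNA sequencing of 30 libraries of Arabidopsis thaliana, mock-treated or submerged in water. The sample fields name whole seedlings aged 6 days, while the extraction text, the same for all 30 libraries, speaks of germinating seeds or 6-day-old seedlings. The libraries form 2 sets with separate Col wild-type controls, which were never fitted together. The bak set has 12 libraries in 4 groups of 3, Col and the double mutant bak1-3 bkk1-1 under both treatments. The tcp set has 18 libraries in 6 groups of 3, Col, the single mutant tcp21 and the multiple mutant tcpq under both treatments. BAK1 and BKK1 encode co-receptor kinases of brassinosteroid and immune receptors, and TCP21, also known as CHE, encodes a class I TCP transcription factor that binds the CCA1 promoter. The series states as its aim to profile these mutants because they are sensitive to submergence. Library totals in the bak set ran from 19662531 to 27417759 counts, and those in the tcp set from 17466180 to 33957452. How long the seedlings were submerged and which genes tcpq lacks are not given in the sources used here. Fold changes are log2 values ± SE, CPM values are means ± SD, and each group has n = 3 libraries. "Rose", "fell" and "called" refer to an edgeR adjusted p below 0.05.

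The first Col mock library of the tcp set carries a genotype field that names bak1-3 bkk1-1, against its title and strain, and was grouped as Col. Its levels of BAK1 and BKK1 were 78.7 and 49.2 CPM, beside 75.3 and 35.6 and 82.2 and 44.2 CPM in the other Col mock libraries of that set. BAK1 in the mock libraries of the double mutant lay between 26 and 29.4 CPM.

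Transcripts of BAK1, BKK1 and TCP21 were the starting point. In mock seedlings of bak1-3 bkk1-1, BAK1 (AT4G33430) reached 28 ± 1.76 CPM against 78 ± 8.67 in Col, and BKK1 (AT2G13790) 13 ± 1.87 against 36.4 ± 6.94. BAK1 was lower by 1.48 ± 0.11 (adjusted p = 4.54e-07) in mock and by 0.77 ± 0.11 (adjusted p = 0.000386) under submergence, with every mutant library under every Col library in mock. BKK1 was lower by 1.49 ± 0.14 (adjusted p = 5.81e-06) and by 1.3 ± 0.14 (adjusted p = 2.18e-05). In tcp21, TCP21 (AT5G08330) was lower by 1.64 ± 0.10 in mock (adjusted p = 3.61e-13) and was lower by 1.75 ± 0.10 under submergence (adjusted p = 4.49e-12). In tcpq it was lower by 2.07 ± 0.10 in mock (adjusted p = 3.01e-15) but only by 0.36 ± 0.10 under submergence (adjusted p = 0.00799). BKK1 was also lower in mock seedlings of tcp21, by 1.18 ± 0.11, and of tcpq, by 1.36 ± 0.11. Under submergence its differences from Col were -0.44 ± 0.10 in tcp21 and -0.40 ± 0.10 in tcpq. BAK1 differed from Col in mock by -0.26 ± 0.07 in tcp21 and -0.33 ± 0.07 in tcpq, and was not called under submergence (adjusted p = 0.806 and 0.485). Transcript levels do not by themselves show how much protein was left. TCP9, another class I TCP gene, had 0 counts in every library.

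Submergence moved these genes as well. BAK1 rose by 0.75 ± 0.11 in Col and 1.46 ± 0.11 in bak1-3 bkk1-1. In the tcp set its rises were 0.24 ± 0.07 in Col, 0.47 ± 0.07 in tcp21 and 0.49 ± 0.07 in tcpq. BKK1 rose by 0.38 ± 0.13 in Col of the bak set, a call lost without library Col mock 2, Col mock 3, Col submergence 2 or Col submergence 3 (adjusted p up to 0.108). Its rise in bak1-3 bkk1-1 was 0.57 ± 0.15. The tcp set gave larger BKK1 rises of 1.24 ± 0.10 in Col, 1.98 ± 0.11 in tcp21 and 2.2 ± 0.11 in tcpq. TCP21 fell by 2.2 ± 0.20 in Col and 1.88 ± 0.20 in bak1-3 bkk1-1. In the tcp set it fell by 0.25 ± 0.09 in Col, a call lost without library Col mock 2, Col mock 3, Col submergence 1 or Col submergence 2 (adjusted p up to 0.149), and by 0.36 ± 0.11 in tcp21, a call lost without library tcp21 submergence 1 (adjusted p = 0.0725). It rose by 1.46 ± 0.10 in tcpq.

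**Figure D1:**
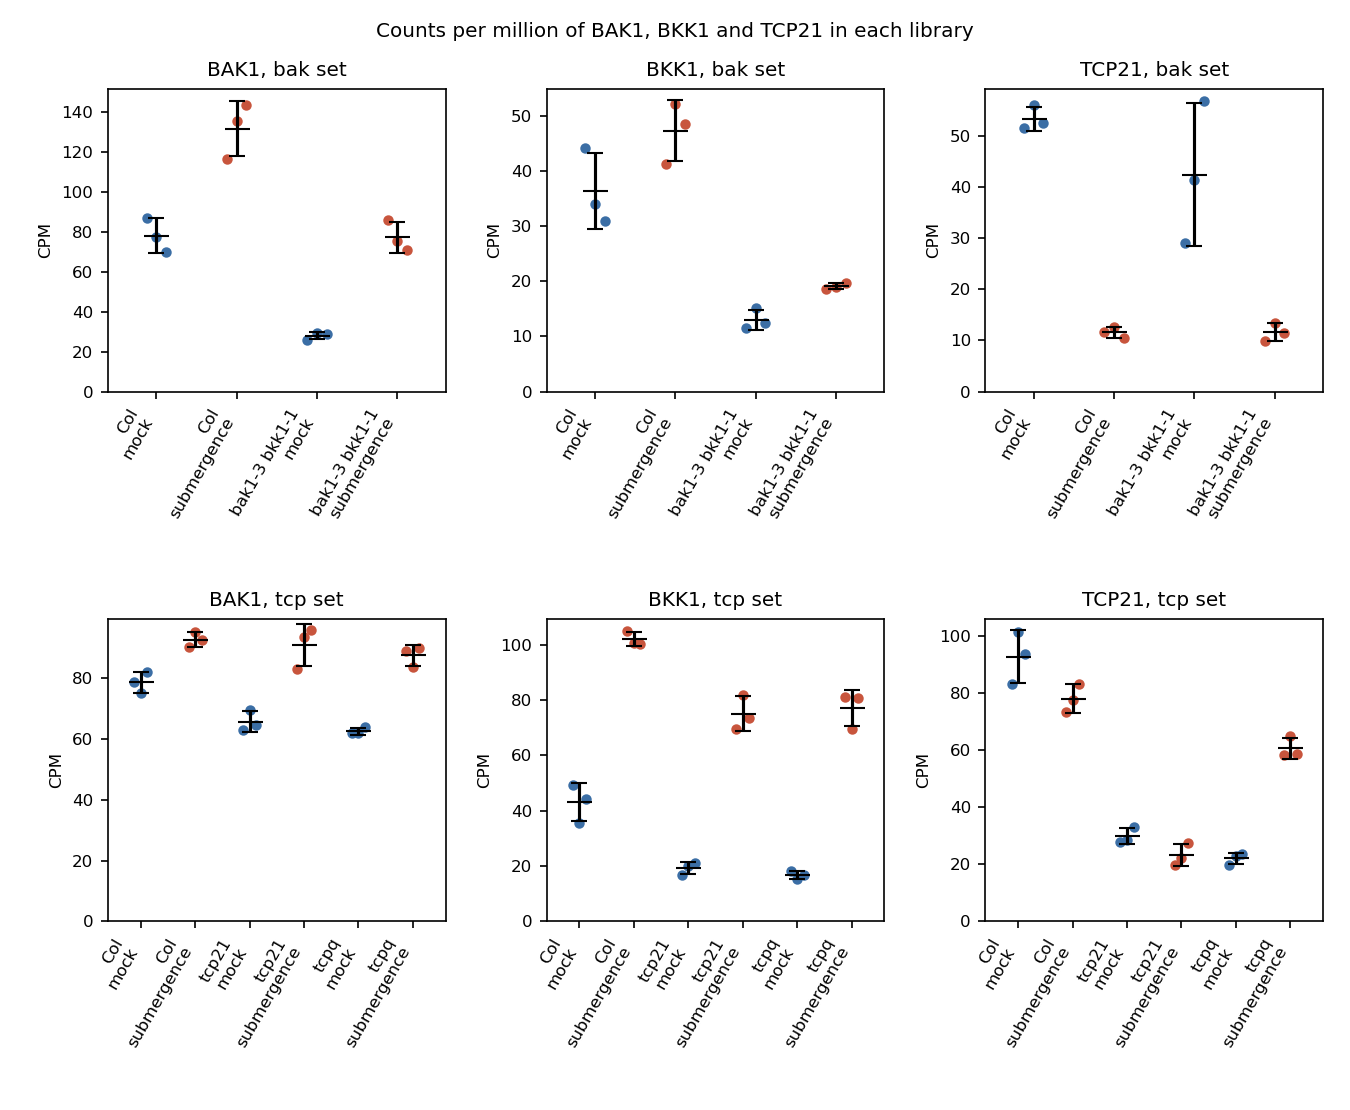
CPM of BAK1, BKK1 and TCP21 per library by group, where points are libraries and the bar with its error is the mean ± SD of n = 3. BAK1 in mock seedlings stood at 28 ± 1.76 CPM in bak1-3 bkk1-1 and at 78 ± 8.67 CPM in Col.

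Submergence was the largest source of variation. The first principal component of log2 CPM held 62.9% of the variance in the bak set and parted all mock libraries (-76.11 to -62.46) from all submergence libraries (48.76 to 80.32). The second held 9% and parted Col (12.7 to 32.69) from bak1-3 bkk1-1 (-31.54 to -19.96). In the tcp set the first component held 45.9%, with mock libraries from -94.87 to -20.64 and submergence libraries from 43.42 to 70.29. Its second component held 18% and spread the mock groups, with tcp21 at 67.63 to 77.37 and tcpq at -52.92 to -47.43. The third held 12.1%, with Col mock at 58.14 to 65.7.

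**Figure D2:**
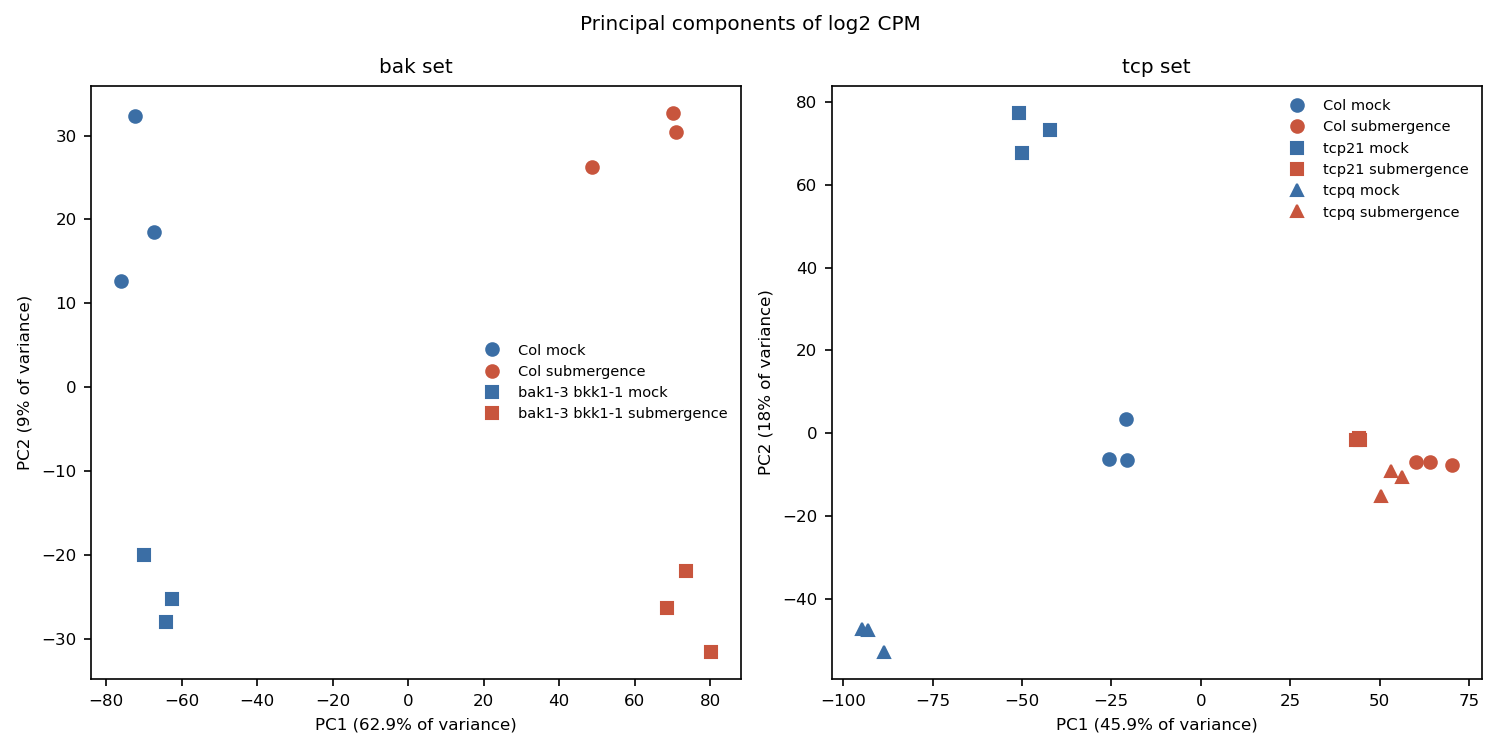
First and second principal components of log2 CPM in each set, with axes in component units and points standing for libraries. Mock and submergence libraries lie on opposite sides of the first component, which holds 62.9% of the variance in the bak set and 45.9% in the tcp set.

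**Figure D3:**
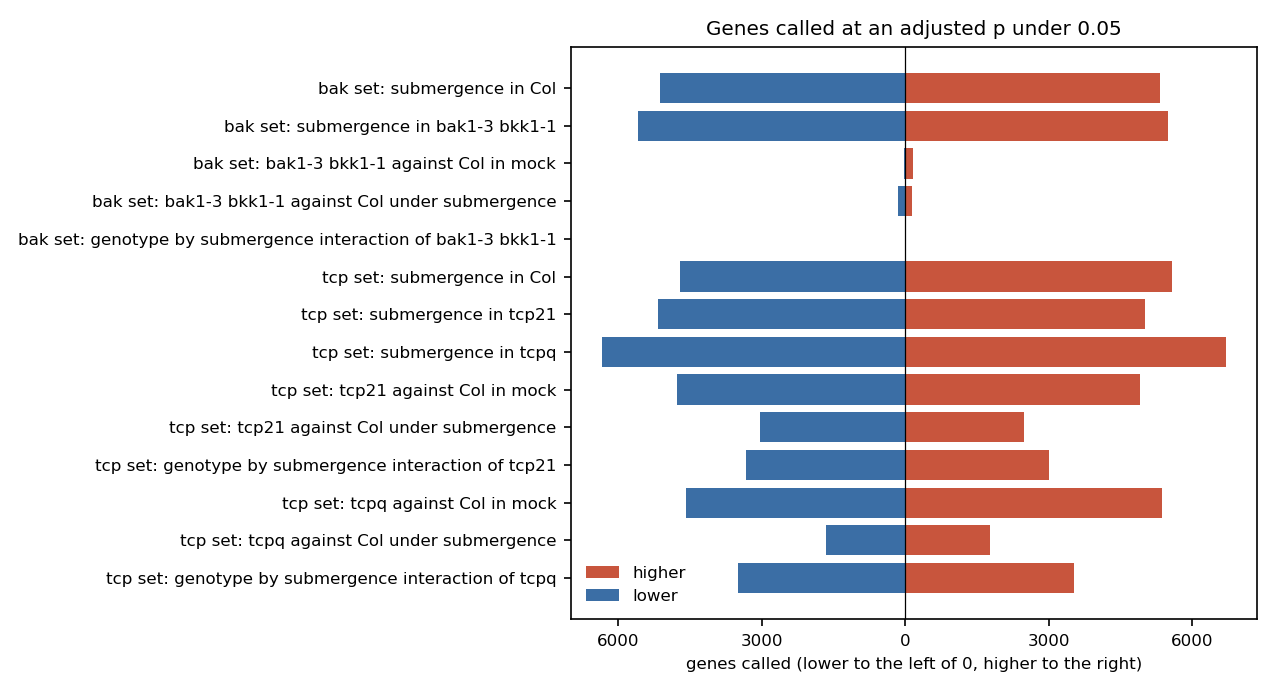
Number of genes called higher and lower in each of the 14 comparisons. The totals run from 13029 for submergence in tcpq to 10 for the interaction in bak1-3 bkk1-1, which became 0 without the first mutant submergence library.

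The first question was how Col of the bak set responded to submergence. Genes of carbon shortage rose, among them DIN3 (AT3G06850) by 2.93 ± 0.15 and ETFQO (AT2G43400) by 1.83 ± 0.12, which serve the breakdown of branched-chain amino acids, and DIN10 (AT5G20250), a raffinose synthase, by 1.97 ± 0.14. On the energy starvation list 14 of 16 measured genes rose and 1 fell (15 and 1 adjusted over the list alone), with camera adjusted p = 1.05e-07, and adjusted p = 0.393 with an estimated correlation. Autophagy genes followed, with ATG8E (AT2G45170) up by 1.98 ± 0.12 and ATG18A (AT3G62770) by 1.45 ± 0.10. Of that list 19 of 20 measured genes rose and 0 fell (19 and 0 adjusted over the list alone), with camera adjusted p = 1.34e-07, and adjusted p = 0.179 with an estimated correlation. Genes of ethylene signalling rose, among them the receptors ERS1 (AT2G40940) by 1.93 ± 0.09 and ETR2 (AT3G23150) by 2.13 ± 0.11 and the kinase CTR1 (AT5G03730) by 2.09 ± 0.10. In the ethylene list 13 of 16 measured genes rose and 1 fell (13 and 1 adjusted over the list alone), with camera adjusted p = 4.62e-06, and adjusted p = 0.0471 with an estimated correlation. The group VII ERF factors, which act in low-oxygen signalling, all rose, for example RAP2.3 (AT3G16770) by 2.03 ± 0.13 and HRE1 (AT1G72360) by 2.19 ± 0.27. For them 4 of 4 measured genes rose and 0 fell (4 and 0 adjusted over the list alone), with camera adjusted p = 0.00103, and adjusted p = 0.393 with an estimated correlation. The senescence regulator ORE1 (AT5G39610) rose by 2.67 ± 0.20 and the chlorophyll breakdown gene NYE1 (AT4G22920) by 1.22 ± 0.14. Among senescence genes 7 of 9 measured genes rose and 0 fell (7 and 0 adjusted over the list alone), with camera adjusted p = 0.00216, and adjusted p = 0.393 with an estimated correlation.

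Growth and photosynthesis genes fell in the same seedlings. The light-harvesting gene LHCB1.1 (AT1G29920) fell by 1.2 ± 0.12 and RCA (AT2G39730), the Rubisco activase, by 1.21 ± 0.14. Of the photosynthesis list 0 of 26 measured genes rose and 24 fell (0 and 24 adjusted over the list alone), with camera adjusted p = 2.32e-07, and adjusted p = 0.541 with an estimated correlation. The cyclin gene CYCD1-1 (AT1G70210) fell by 1.97 ± 0.15 and the replication clamp gene PCNA1 (AT1G07370) by 1.73 ± 0.18. Of cell cycle genes 0 of 19 measured genes rose and 13 fell (0 and 14 adjusted over the list alone), with camera adjusted p = 9.52e-05, and adjusted p = 0.513 with an estimated correlation. Aliphatic glucosinolate synthesis fell, with CYP79F1 (AT1G16410) down by 5.66 ± 0.20 and CYP83A1 (AT4G13770) by 2.43 ± 0.15. In that list 2 of 14 measured genes rose and 12 fell (2 and 12 adjusted over the list alone), with camera adjusted p = 2.86e-05, and adjusted p = 0.393 with an estimated correlation. The anthocyanin gene LDOX (AT4G22880) fell by 2.22 ± 0.25, and of the flavonoid list 2 of 11 measured genes rose and 8 fell (2 and 8 adjusted over the list alone), with camera adjusted p = 0.00864, and adjusted p = 0.393 with an estimated correlation. Of cytosolic ribosomal protein genes 25 of 283 measured genes rose and 127 fell (26 and 127 adjusted over the list alone), with camera adjusted p = 3.96e-05, and adjusted p = 0.622 with an estimated correlation.

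The core hypoxia genes went both ways in Col of the bak set. The fermentation genes PDC2 (AT5G54960) and ADH1 (AT1G77120) rose by 1.04 ± 0.10 and 0.77 ± 0.21. The other pyruvate decarboxylase gene PDC1 (AT4G33070) fell by 1.58 ± 0.28, the sucrose synthase gene SUS4 (AT3G43190) by 3.22 ± 0.34 and the oxygen sensor gene PCO1 (AT5G15120) by 2.03 ± 0.28. Of the list 12 of 30 measured genes rose and 9 fell (12 and 13 adjusted over the list alone), with camera adjusted p = 0.981, and adjusted p = 0.988 with an estimated correlation. The largest rises of single genes included AT5G25260, a membrane-associated band 7 protein, by 7.4 ± 0.32, and the jasmonate sulfotransferase gene ST2A (AT5G07010) by 6.77 ± 0.28. AT2G38240, an oxygenase gene, went from 0.106 ± 0.0919 to 416 ± 163 CPM. Among the largest falls were transcription factor genes of cold and stress responses, CBF2 (AT4G25470) by 6.29 ± 0.42, DDF1 (AT1G12610) by 6.03 ± 1.14 and ORA47 (AT1G74930) by 6.00 ± 0.44. In all, 5317 genes rose and 5124 fell, of which 3662 changed at least 2-fold.

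The remaining lists gave these calls for submergence in Col of the bak set. Hormone lists came out as follows, jasmonate with 4 higher and 8 lower of 18 (4 and 8 adjusted over the list alone), abscisic acid with 6 higher and 8 lower of 15 (6 and 8 adjusted over the list alone) and auxin-induced genes with 2 higher and 1 lower of 6 (2 and 1 adjusted over the list alone). SERK receptor kinases and brassinosteroid signalling had 4 higher and 4 lower of 9 (4 and 4 adjusted over the list alone), brassinosteroid synthesis had 4 higher and 4 lower of 10 (4 and 4 adjusted over the list alone) and brassinosteroid-induced genes had 3 higher and 3 lower of 8 (3 and 3 adjusted over the list alone). Of defence genes, salicylic acid defence showed 4 higher and 8 lower of 25 (4 and 8 adjusted over the list alone) and pattern-triggered immunity 8 higher and 5 lower of 16 (9 and 5 adjusted over the list alone). Class I TCP factors showed 1 higher and 4 lower of 9 (1 and 4 adjusted over the list alone) and the circadian clock 6 higher and 7 lower of 19 (6 and 7 adjusted over the list alone). Stress lists gave 5 higher and 1 lower of 12 (6 and 1 adjusted over the list alone) for heat shock, 6 higher and 0 lower of 8 (6 and 0 adjusted over the list alone) for ER folding and 3 higher and 9 lower of 16 (3 and 9 adjusted over the list alone) for reactive oxygen. Cytosolic glycolysis gave 1 higher and 6 lower of 12 (1 and 6 adjusted over the list alone). Tissue markers gave 3 higher and 1 lower of 16 (3 and 1 adjusted over the list alone) for root, 3 higher and 0 lower of 6 (5 and 0 adjusted over the list alone) for the stomatal lineage and 2 higher and 0 lower of 10 (0 and 0 adjusted over the list alone) for seed storage. The seed storage list passed the preset test, with camera adjusted p = 0.0314, and adjusted p = 0.644 with an estimated correlation. The second Col mock library stood apart there, as its seed storage genes summed to 296 CPM, above each of the submerged Col libraries. Signs of the median, mean and list test were not all alike for the lists abscisic acid and water deficit, brassinosteroid synthesis and inactivation and brassinosteroid-induced genes, with camera adjusted p of at least 0.864.

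The response of bak1-3 bkk1-1 to submergence was close to that of Col. Autophagy, starvation and ethylene genes rose again, among them ATG8E by 1.95 ± 0.12, DIN10 by 2.21 ± 0.14 and ETR2 by 2 ± 0.11. In the autophagy list 20 of 20 measured genes rose and 0 fell (20 and 0 adjusted over the list alone), with camera adjusted p = 6.51e-08, and adjusted p = 0.178 with an estimated correlation. In the starvation list 14 of 16 measured genes rose and 1 fell (14 and 1 adjusted over the list alone), with camera adjusted p = 4.04e-08, and adjusted p = 0.366 with an estimated correlation. For ethylene genes 13 of 16 measured genes rose and 2 fell (13 and 2 adjusted over the list alone), with camera adjusted p = 3.11e-06, and adjusted p = 0.0452 with an estimated correlation. On the heat shock list 9 of 12 measured genes rose and 0 fell (9 and 0 adjusted over the list alone), with camera adjusted p = 0.00354, and adjusted p = 0.383 with an estimated correlation. Photosynthesis genes fell, as 0 of 26 measured genes rose and 25 fell (0 and 25 adjusted over the list alone), with camera adjusted p = 1.7e-09, and adjusted p = 0.366 with an estimated correlation. Of ribosomal protein genes 15 of 283 measured genes rose and 175 fell (15 and 176 adjusted over the list alone), with camera adjusted p = 1.63e-09, and adjusted p = 0.366 with an estimated correlation. Of the cell cycle list 0 of 19 measured genes rose and 18 fell (0 and 18 adjusted over the list alone), with camera adjusted p = 8.46e-06, and adjusted p = 0.366 with an estimated correlation. Large single rises were those of the dirigent gene DIR5 (AT1G64160) by 6.67 ± 0.48, the ERF gene ABR1 (AT5G64750) by 6.44 ± 0.66 and the sugar transporter gene SWEET10 (AT5G50790) by 6.29 ± 0.38. The cytochrome P450 gene CYP71A27 (AT4G20240) fell by 5.67 ± 0.33. AT1G06100, a desaturase gene, went from 6.98 ± 1.15 CPM to 0 CPM. Altogether 5484 genes rose and 5588 fell. Across genes, the fold changes of both genotypes had a Pearson r of 0.857, where genes are not independent replicates, and 8693 genes were called in the same direction against 6 in opposite directions. For the lists abscisic acid and water deficit, brassinosteroid-induced genes, core hypoxia genes, jasmonate synthesis and response and root tissue markers, the sign differed between median, mean and test, with camera adjusted p of at least 0.76.

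Mock seedlings of bak1-3 bkk1-1 were compared with Col to see what the mutant lacks or gains without submergence. Salicylic acid defence genes were raised. The pathogenesis gene PR2 (AT3G57260) stood at 19.3 ± 7.19 against 0.0387 ± 0.0372 CPM in Col, and PR5 (AT1G75040) was higher by 1.99 ± 0.27. Genes of salicylic acid synthesis were higher, PBS3 (AT5G13320) by 4.00 ± 0.43 and the regulator SARD1 (AT1G73805) by 2.34 ± 0.21. In this list 11 of 25 measured genes were higher and 0 lower (13 and 0 adjusted over the list alone), with camera adjusted p = 1.96e-18, and adjusted p = 0.0611 with an estimated correlation. The defence-linked genes LURP1 (AT2G14560) and PCC1 (AT3G22231) reached 31.7 ± 12.2 and 19.9 ± 8.38 CPM against 0.117 ± 0.167 and 0.103 ± 0.178 CPM in Col. AT3G22235, a cysteine-rich stress protein gene, was higher by 5.36 ± 0.25, and the senescence gene SAG13 (AT2G29350) by 4.22 ± 0.52. Few genes were lower, among them the cytochrome P450 gene CYP71A19 (AT4G13290) by 1.63 ± 0.27 and the nicotianamine synthase gene NAS3 (AT1G09240) by 1.54 ± 0.21. Jasmonate genes had no call, as 0 of 18 measured genes were higher and 0 lower (0 and 1 adjusted over the list alone), while the list tested lower with camera adjusted p = 2.77e-05, and adjusted p = 0.448 with an estimated correlation. TCP21 was not called (adjusted p = 0.604). There were 195 calls, 165 higher and 30 lower, and 322 with DESeq2, 250 higher and 72 lower. The count was 124 without the second mutant mock library, and it was 226 without the third Col mock library, with 131 higher and 95 lower, so the share of higher genes moved from 84.6% to 58%. The median, mean and test direction differed in sign for the lists class I TCP factors, cytosolic glycolysis, group VII ERF factors and reactive oxygen and antioxidant, with camera adjusted p of at least 0.573.

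Under submergence the same defence genes stayed higher in bak1-3 bkk1-1 than in Col. PBS3 was higher by 3.61 ± 0.27, the salicylic acid synthesis gene ICS1 (AT1G74710) by 1.05 ± 0.14 and the systemic resistance gene FMO1 (AT1G19250) by 4.1 ± 0.55. PR2 stood at 9.52 ± 1.1 against 0.0973 ± 0.0843 CPM. For salicylic acid defence 9 of 25 measured genes were higher and 0 lower (13 and 0 adjusted over the list alone), with camera adjusted p = 3.47e-14, and adjusted p = 0.138 with an estimated correlation. Of genes of pattern-triggered immunity 2 of 16 measured genes were higher and 0 lower (2 and 0 adjusted over the list alone), with camera adjusted p = 0.000183, and adjusted p = 0.217 with an estimated correlation. The starch-related gene QQS (AT3G30720) was higher by 3.06 ± 0.39. The photosynthesis gene LHCB2.2 (AT2G05070) was lower by 0.60 ± 0.12, and in its list 0 of 26 measured genes were higher and 4 lower (0 and 15 adjusted over the list alone), with camera adjusted p = 1.94e-12, and adjusted p = 0.374 with an estimated correlation. In the ribosomal list 1 of 283 measured genes were higher and 7 lower (1 and 85 adjusted over the list alone), with camera adjusted p = 1.22e-22, and adjusted p = 0.217 with an estimated correlation. The flavonol synthase gene FLS1 (AT5G08640) was lower by 0.89 ± 0.12 and chalcone isomerase CHI (AT3G55120) by 0.84 ± 0.13, and of flavonoid genes 0 of 11 measured genes were higher and 3 lower (0 and 6 adjusted over the list alone), with camera adjusted p = 1.05e-05, and adjusted p = 0.217 with an estimated correlation. AT5G38020, a methyltransferase gene, was lower by 2.39 ± 0.36. The fall of EPR1 (AT2G27380), a seed endosperm gene, by 7.19 ± 1.28 was not called without library Col submergence 1, bak1-3 bkk1-1 submergence 1 or bak1-3 bkk1-1 submergence 3 (adjusted p up to 0.103).

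Seed storage transcripts moved with these groups. The 10 seed storage genes summed to 279, 151 and 221 CPM in the Col submergence libraries and to 0.935, 2.07 and 0.228 CPM in those of the mutant. In mock they summed to 1.63, 296 and 1.39 CPM in Col and to 11, 0.389 and 0.0882 CPM in the mutant. Under submergence 0 of 10 measured genes were higher and 1 lower (0 and 9 adjusted over the list alone), with camera adjusted p = 3.46e-12, and adjusted p = 0.217 with an estimated correlation. In total 134 genes were higher and 151 lower in the mutant under submergence, while DESeq2 gave 278 higher and 390 lower, and the 285 calls became 184 without the first mutant submergence library, with the share of higher genes at 58.2% in place of 47%. TCP21 was not called (adjusted p = 0.991). Signs of the median, mean and list test were not all alike for the lists abscisic acid and water deficit, class I TCP factors and jasmonate synthesis and response, with camera adjusted p of at least 0.616.

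The interaction asks which genes responded to submergence differently in bak1-3 bkk1-1 and Col. AT2G22510, a cell wall protein gene, fell further in the mutant, by 1.81 ± 0.25 (adjusted p = 0.0109), from 29 ± 3.47 to 4.56 ± 0.601 CPM against 22.2 ± 3.23 to 12 ± 2.95 CPM in Col. AT2G41090, a calcium-binding protein gene, had an interaction of -1.27 ± 0.18, with 82.6 ± 11.7 and 47 ± 7.22 CPM in mock and submerged mutants and 34.9 ± 2.17 and 47.9 ± 6.05 in Col. The cell wall enzyme gene XTH20 (AT5G48070) had -2 ± 0.33 and the carnitine transporter gene OCT3 (AT1G16390) 0.81 ± 0.14. Only 10 genes were called, 2 higher and 8 lower, with 1579 at an unadjusted p below 0.05 and 95 with DESeq2. None was called without the first mutant submergence library (1406 at an unadjusted p below 0.05 and 70 with DESeq2), and the count reached 11 without the third Col submergence library. Each named gene lost its call without at least 1 library. With a replicate block XTH20 (adjusted p = 0.0566) and OCT3 (adjusted p = 0.0733) were not called, nor was OCT3 with RLE size factors (adjusted p = 0.0508). BAK1 itself had 0.71 ± 0.15 (adjusted p = 0.142), and DESeq2 called it (adjusted p = 0.0113). BKK1 (adjusted p = 0.86) and TCP21 (adjusted p = 0.823) were not called. In the ribosomal list 0 of 283 measured genes were higher and 0 lower (0 and 0 adjusted over the list alone), with camera adjusted p = 7.45e-11, and adjusted p = 0.526 with an estimated correlation. The clock list had no called gene, as 0 of 19 measured genes were higher and 0 lower (3 and 0 adjusted over the list alone), with camera adjusted p = 0.000287, and adjusted p = 0.526 with an estimated correlation. At this depth, spread and number of libraries, the method recovered 43 of 100 simulated 2-fold interactions. For the lists brassinosteroid-induced genes, class I TCP factors, glucosinolate synthesis, reactive oxygen and antioxidant and senescence and chlorophyll breakdown, the sign differed between median, mean and test, with camera adjusted p of at least 0.621.

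The next question was how Col of the tcp set responded to submergence. Jasmonate genes rose, among them the synthesis genes AOC1 (AT3G25760) by 3.15 ± 0.13 and AOC2 (AT3G25770) by 3.76 ± 0.15 and the repressor genes JAZ9 (AT1G70700) by 3.11 ± 0.08 and JAZ10 (AT5G13220) by 3.22 ± 0.15. Of this list 17 of 18 measured genes rose and 0 fell (17 and 0 adjusted over the list alone), with camera adjusted p = 1.08e-11, and adjusted p = 0.23 with an estimated correlation. Glucosinolate genes rose, such as MAM1 (AT5G23010) by 3.27 ± 0.20 and BCAT4 (AT3G19710) by 4.81 ± 0.32, and 12 of 14 measured genes rose and 1 fell (12 and 1 adjusted over the list alone), with camera adjusted p = 4.18e-06, and adjusted p = 0.292 with an estimated correlation. Photosynthesis genes rose, for example RBCS2B (AT5G38420) by 0.96 ± 0.08, and 23 of 26 measured genes rose and 0 fell (23 and 0 adjusted over the list alone), with camera adjusted p = 2.65e-05, and adjusted p = 0.716 with an estimated correlation. The mitotic gene CDKB2-2 (AT1G20930) rose by 1.68 ± 0.16, and in the cell cycle list 13 of 19 measured genes rose and 0 fell (13 and 0 adjusted over the list alone), with camera adjusted p = 0.00038, and adjusted p = 0.23 with an estimated correlation. Heat shock genes also rose, as 10 of 14 measured genes rose and 0 fell (10 and 0 adjusted over the list alone), with camera adjusted p = 0.00389, and adjusted p = 0.642 with an estimated correlation. Of the core hypoxia genes 9 of 30 measured genes rose and 8 fell (10 and 8 adjusted over the list alone), with camera adjusted p = 0.773, and adjusted p = 0.934 with an estimated correlation, and PDC2 rose by 1.41 ± 0.14 and ADH1 by 1.49 ± 0.29. The root iron transporter gene IRT1 (AT4G19690) went from 0 CPM to 11.9 ± 0.274 CPM. AT2G38240 rose by 6.64 ± 0.21. The largest falls included the auxin-responsive SAUR gene AT4G38860 by 5.02 ± 0.22, NAS3 by 4.39 ± 0.34 and the expansin gene EXPA8 (AT2G40610) by 3.11 ± 0.34. Here 5576 genes rose and 4711 fell, 2789 of them at least 2-fold. The median, mean and test direction differed in sign for the lists abscisic acid and water deficit, pattern-triggered immunity and SERK receptor kinases and brassinosteroid signalling, with camera adjusted p of at least 0.735.

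In tcp21, submergence raised jasmonate genes as well, AOC2 by 2.80 ± 0.14 and JAZ10 by 3.78 ± 0.18, and 16 of 18 measured genes rose and 0 fell (16 and 0 adjusted over the list alone), with camera adjusted p = 5.25e-11, and adjusted p = 0.291 with an estimated correlation. Starvation genes rose in tcp21, among them DIN10 by 2.49 ± 0.16 and the trehalose phosphate synthase-like gene TPS8 (AT1G70290) by 3.11 ± 0.18. In the starvation list 14 of 16 measured genes rose and 0 fell (14 and 0 adjusted over the list alone), with camera adjusted p = 6.46e-08, and adjusted p = 0.376 with an estimated correlation. Of ribosomal protein genes 136 of 284 measured genes rose and 14 fell (136 and 14 adjusted over the list alone), with camera adjusted p = 1.08e-05, and adjusted p = 0.712 with an estimated correlation. For heat shock genes 10 of 14 measured genes rose and 0 fell (12 and 0 adjusted over the list alone), with camera adjusted p = 0.000458, and adjusted p = 0.291 with an estimated correlation. The ERF gene DDF1, which restrains growth under stress, went from 0.113 ± 0.196 to 33.4 ± 7.6 CPM, and ABR1 rose by 6.87 ± 0.34. The expansin genes EXPA8 and EXPA15 (AT2G03090) fell by 4.41 ± 0.38 and 4.34 ± 0.27. The cysteine protease gene AT2G27420 fell by 4.11 ± 0.18. The comparison gave 5000 rises and 5172 falls. Signs of the median, mean and list test were not all alike for the lists abscisic acid and water deficit, cell cycle, class I TCP factors, ER folding, reactive oxygen and antioxidant, seed storage markers and senescence and chlorophyll breakdown, with camera adjusted p of at least 0.996.

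In tcpq, submergence changed the most genes, 6697 up and 6332 down. Jasmonate genes rose, for example CYP94C1 (AT2G27690), which inactivates jasmonoyl-isoleucine, by 7.79 ± 0.33, and 18 of 18 measured genes rose and 0 fell (18 and 0 adjusted over the list alone), with camera adjusted p = 4.08e-10, and adjusted p = 0.305 with an estimated correlation. The repressor gene JAZ8 (AT1G30135) went from 0.014 ± 0.0243 to 11.7 ± 2.47 CPM. On the photosynthesis list 25 of 26 measured genes rose and 1 fell (25 and 1 adjusted over the list alone), with camera adjusted p = 2.76e-08, and adjusted p = 0.39 with an estimated correlation. Salicylic acid defence genes rose too, as 18 of 22 measured genes rose and 0 fell (18 and 0 adjusted over the list alone), with camera adjusted p = 0.000227, and adjusted p = 0.305 with an estimated correlation. Ribosomal protein genes mostly fell, as 39 of 284 measured genes rose and 161 fell (39 and 162 adjusted over the list alone), with camera adjusted p = 2.56e-06, and adjusted p = 0.536 with an estimated correlation. In ER folding 1 of 8 measured genes rose and 7 fell (1 and 7 adjusted over the list alone), with camera adjusted p = 0.00227, and adjusted p = 0.305 with an estimated correlation. Genes of cell wall growth were among the largest falls, XTH31 (AT3G44990) by 5.02 ± 0.12 and EXPA8 by 5.12 ± 0.34, next to EARLI1 (AT4G12480), a lipid-transfer protein gene, by 5.04 ± 0.20 and NAS3 by 5.28 ± 0.29. For the lists auxin-induced genes, circadian clock, ethylene synthesis and signalling, group VII ERF factors and senescence and chlorophyll breakdown, the sign differed between median, mean and test, with camera adjusted p of at least 0.404.

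Mock seedlings of tcp21 differed widely from Col. Starvation genes were lower, the beta-glucosidase gene DIN2 (AT3G60140) by 2.01 ± 0.17 and TPS8 by 1.79 ± 0.18, and 0 of 16 measured genes were higher and 16 lower (0 and 16 adjusted over the list alone), with camera adjusted p = 1.7e-08, and adjusted p = 0.228 with an estimated correlation. Cell cycle genes were higher, as 17 of 19 measured genes were higher and 0 lower (17 and 0 adjusted over the list alone), with camera adjusted p = 8.83e-07, and adjusted p = 0.0794 with an estimated correlation. Of photosynthesis genes 21 of 26 measured genes were higher and 0 lower (22 and 0 adjusted over the list alone), with camera adjusted p = 2.98e-06, and adjusted p = 0.29 with an estimated correlation. Glycolysis genes were higher, PGK3 (AT1G79550) by 0.98 ± 0.08 and GAPC1 (AT3G04120) by 0.84 ± 0.07, and 10 of 12 measured genes were higher and 0 lower (10 and 0 adjusted over the list alone), with camera adjusted p = 3.52e-05, and adjusted p = 0.228 with an estimated correlation. The glucosinolate genes MAM1 and CYP83A1 were higher by 3.49 ± 0.19 and 5.37 ± 0.35, and in their list 10 of 14 measured genes were higher and 3 lower (10 and 3 adjusted over the list alone), with camera adjusted p = 0.000131, and adjusted p = 0.228 with an estimated correlation. Clock genes were changed, PRR9 (AT2G46790) by 2.45 ± 0.10 and GI (AT1G22770) by 1.94 ± 0.12, and 11 of 18 measured genes were higher and 3 lower (11 and 3 adjusted over the list alone), with camera adjusted p = 0.00338, and adjusted p = 0.228 with an estimated correlation. IRT1 stood at 13.3 ± 4.24 CPM against 0 CPM in Col, while the ERF gene ddf2 (AT1G63030) was at 0 CPM against 7.01 ± 1.74. SRO5 (AT5G62520), a stress gene, was lower by 5.77 ± 0.27 and JAZ7 (AT2G34600) by 4.55 ± 0.24. Chloroplast-encoded genes took 0.237%, 0.22% and 0.564% of counts in the tcp21 mock libraries, against 0.0351%, 0.029% and 0.0365% in Col mock. There were 4899 genes higher and 4769 lower. The median, mean and test direction differed in sign for the lists brassinosteroid synthesis and inactivation, ER folding and seed storage markers, with camera adjusted p of at least 0.639.

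Under submergence tcp21 differed from Col in fewer genes. Jasmonate genes were lower, as 0 of 18 measured genes were higher and 16 lower (0 and 16 adjusted over the list alone), with camera adjusted p = 4.22e-10, and adjusted p = 0.166 with an estimated correlation. The jasmonate-induced aminotransferase gene TAT3 (AT2G24850) was lower by 4.50 ± 0.35 and the methyltransferase gene FAMT (AT3G44860) was lower by 3.10 ± 0.23. In pattern-triggered immunity 0 of 15 measured genes were higher and 9 lower (0 and 11 adjusted over the list alone), with camera adjusted p = 0.000185, and adjusted p = 0.166 with an estimated correlation. Starvation genes were higher, as 9 of 16 measured genes were higher and 0 lower (11 and 0 adjusted over the list alone), with camera adjusted p = 0.000185, and adjusted p = 0.453 with an estimated correlation. Of glycolysis genes 7 of 12 measured genes were higher and 0 lower (7 and 0 adjusted over the list alone), with camera adjusted p = 0.000548, and adjusted p = 0.33 with an estimated correlation. The ferric reductase gene FRO5 (AT5G23990) was higher by 3.13 ± 0.16 and the small heat shock gene HSP17.6II (AT5G12020) by 2.3 ± 0.44. The count was 2480 higher and 3025 lower, and its total of 5505 became 3441 without the third Col submergence library. Chloroplast-encoded genes took 0.0997%, 0.0917% and 0.238% of counts in tcp21 and 0.0303%, 0.0296% and 0.0374% in Col. Signs of the median, mean and list test were not all alike for the lists core hypoxia genes, ethylene synthesis and signalling and group VII ERF factors, with camera adjusted p of at least 0.422.

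The tcp21 interaction asks where the submergence response of tcp21 departed from that of Col. Starvation genes had positive interactions, DIN2 of 2.13 ± 0.24 and TPS8 of 1.80 ± 0.24, and 15 of 16 measured genes were higher and 0 lower (16 and 0 adjusted over the list alone), with camera adjusted p = 4.81e-13, and adjusted p = 0.323 with an estimated correlation. Glucosinolate genes had negative ones, for example MAM1 of -3.74 ± 0.24 and CYP83A1 of -5.98 ± 0.47, and 0 of 14 measured genes were higher and 10 lower (1 and 10 adjusted over the list alone), with camera adjusted p = 1.9e-07, and adjusted p = 0.27 with an estimated correlation. For cell cycle genes 0 of 19 measured genes were higher and 12 lower (0 and 14 adjusted over the list alone), with camera adjusted p = 4.51e-05, and adjusted p = 0.231 with an estimated correlation. SRO5 had an interaction of 4.65 ± 0.35, going from 0.963 ± 0.517 to 18.9 ± 4.72 CPM in tcp21 and from 47 ± 7.16 to 40.9 ± 5.09 in Col. IRT1 stood at 10.4 ± 3.6 CPM in submerged tcp21 and 11.9 ± 0.274 in submerged Col, against 13.3 ± 4.24 and 0 CPM in mock. BKK1 had 0.74 ± 0.15 (adjusted p = 0.000303), while BAK1 (adjusted p = 0.0758) and TCP21 (adjusted p = 0.604) were not called. BAK1 was called without library tcp21 mock 2 (adjusted p = 0.0347) or tcp21 submergence 1 (adjusted p = 0.0254), with RLE size factors (adjusted p = 0.0457) and with DESeq2 (adjusted p = 0.0338). The interaction had 2997 genes higher and 3317 lower. With RLE size factors it had 3300 higher and 3025 lower, and with DESeq2 3307 and 3000, so this balance depends on the processing. For the lists auxin-induced genes, heat shock proteins and factors and jasmonate synthesis and response, the sign differed between median, mean and test, with camera adjusted p of at least 0.438.

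Mock seedlings of tcpq were also far from Col, partly in other directions than tcp21. Salicylic acid defence genes were lower, among them the immune receptor gene ADR1-L2 (AT5G04720) by 1.60 ± 0.09 and EDS1 (AT3G48090), a lipase-like immune regulator, by 1.14 ± 0.10, and 0 of 22 measured genes were higher and 18 lower (0 and 18 adjusted over the list alone), with camera adjusted p = 1.69e-08, and adjusted p = 0.177 with an estimated correlation. Jasmonate genes were mostly lower, as 3 of 18 measured genes were higher and 13 lower (3 and 14 adjusted over the list alone), with camera adjusted p = 7.65e-07, and adjusted p = 0.226 with an estimated correlation. Photosynthesis genes were lower, PSBO2 (AT3G50820) by 0.75 ± 0.07, and 1 of 26 measured genes were higher and 24 lower (1 and 25 adjusted over the list alone), with camera adjusted p = 6.22e-08, and adjusted p = 0.312 with an estimated correlation. Ribosomal protein genes were higher, as 165 of 284 measured genes were higher and 21 lower (167 and 24 adjusted over the list alone), with camera adjusted p = 8.94e-09, and adjusted p = 0.344 with an estimated correlation. The ER chaperone gene BIP2 (AT5G42020) was higher by 2.26 ± 0.09, and of ER folding genes 6 of 8 measured genes were higher and 1 lower (6 and 1 adjusted over the list alone), with camera adjusted p = 0.00132, and adjusted p = 0.226 with an estimated correlation. The abscisic acid hydroxylase gene CYP707A2 (AT2G29090) was higher by 5.32 ± 0.18, EARLI1 by 5.15 ± 0.20 and the expansin gene EXPA17 (AT4G01630) by 4.21 ± 0.33. The thionin genes THI2.2 (AT5G36910) and AT1G66100 were lower by 6.53 ± 0.22 and 6.43 ± 0.24, and ddf2 was at 0 CPM. Chloroplast-encoded genes took 0.0382%, 0.0655% and 0.0472% of counts. The comparison had 5371 genes higher and 4587 lower. The median, mean and test direction differed in sign for the lists abscisic acid and water deficit, core hypoxia genes, seed storage markers and senescence and chlorophyll breakdown, with camera adjusted p of at least 0.524.

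Submerged tcpq showed lower jasmonate genes than submerged Col, as 0 of 18 measured genes were higher and 17 lower (0 and 17 adjusted over the list alone), with camera adjusted p = 3.88e-14, and adjusted p = 0.117 with an estimated correlation. TAT3 was lower by 3.09 ± 0.29 and THI2.2 by 3.38 ± 0.16. The lipase-like gene AT5G33370 was lower by 4.81 ± 0.44 and GPAT2 (AT1G02390), an acyltransferase gene, by 3.25 ± 0.33. Heat shock genes were higher, HSP17.6II by 2.73 ± 0.43, and 8 of 14 measured genes were higher and 0 lower (9 and 0 adjusted over the list alone), with camera adjusted p = 4.63e-05, and adjusted p = 0.174 with an estimated correlation. In pattern-triggered immunity 0 of 15 measured genes were higher and 9 lower (0 and 10 adjusted over the list alone), with camera adjusted p = 4.63e-05, and adjusted p = 0.117 with an estimated correlation. Of glucosinolate genes 0 of 14 measured genes were higher and 8 lower (0 and 9 adjusted over the list alone), with camera adjusted p = 0.000317, and adjusted p = 0.305 with an estimated correlation. The glyoxylate cycle gene ICL (AT3G21720) was higher by 2.49 ± 0.23, the expansin gene EXPA16 (AT3G55500) by 3.02 ± 0.20 and FRO5 by 2.85 ± 0.16. In all 1775 genes were higher and 1665 lower. Signs of the median, mean and list test were not all alike for the lists brassinosteroid-induced genes, cell cycle and group VII ERF factors, with camera adjusted p of at least 0.806.

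For the tcpq interaction, ribosomal protein genes were mostly negative, as 5 of 284 measured genes were higher and 145 lower (9 and 157 adjusted over the list alone), with camera adjusted p = 1.51e-12, and adjusted p = 0.276 with an estimated correlation. Salicylic acid defence genes were positive, ADR1-L2 with 1.66 ± 0.12 and EDS1 with 0.93 ± 0.15, and 14 of 22 measured genes were higher and 0 lower (14 and 0 adjusted over the list alone), with camera adjusted p = 2.35e-06, and adjusted p = 0.27 with an estimated correlation. Photosynthesis genes were positive as well, as 23 of 26 measured genes were higher and 1 lower (23 and 1 adjusted over the list alone), with camera adjusted p = 2.47e-06, and adjusted p = 0.335 with an estimated correlation. RAS1 (AT1G09950), a salt and abscisic acid response gene, had 6.16 ± 0.40, going from 0.153 ± 0.0309 to 23 ± 3.51 CPM in tcpq and from 11.1 ± 2.55 to 22.7 ± 1.89 in Col. XTH20 had -4.26 ± 0.48. TCP21 had 1.71 ± 0.14 (adjusted p = 2.03e-10) and BKK1 0.96 ± 0.15 (adjusted p = 8.75e-06), while BAK1 was not called (adjusted p = 0.0535). It was called without library Col mock 2 (adjusted p = 0.0411) or tcpq submergence 2 (adjusted p = 0.0452), with RLE size factors (adjusted p = 0.0386), the stricter filter (adjusted p = 0.0475), only the compared groups in the fit (adjusted p = 0.0277) and DESeq2 (adjusted p = 0.0274). The call of AT2G41810 was lost without library Col mock 1, Col mock 2, Col submergence 1, Col submergence 3 or tcpq submergence 1 (adjusted p up to 0.403). There were 3534 higher and 3489 lower genes. For the lists core hypoxia genes, heat shock proteins and factors and root tissue markers, the sign differed between median, mean and test, with camera adjusted p of at least 0.56.

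**Figure D4:**
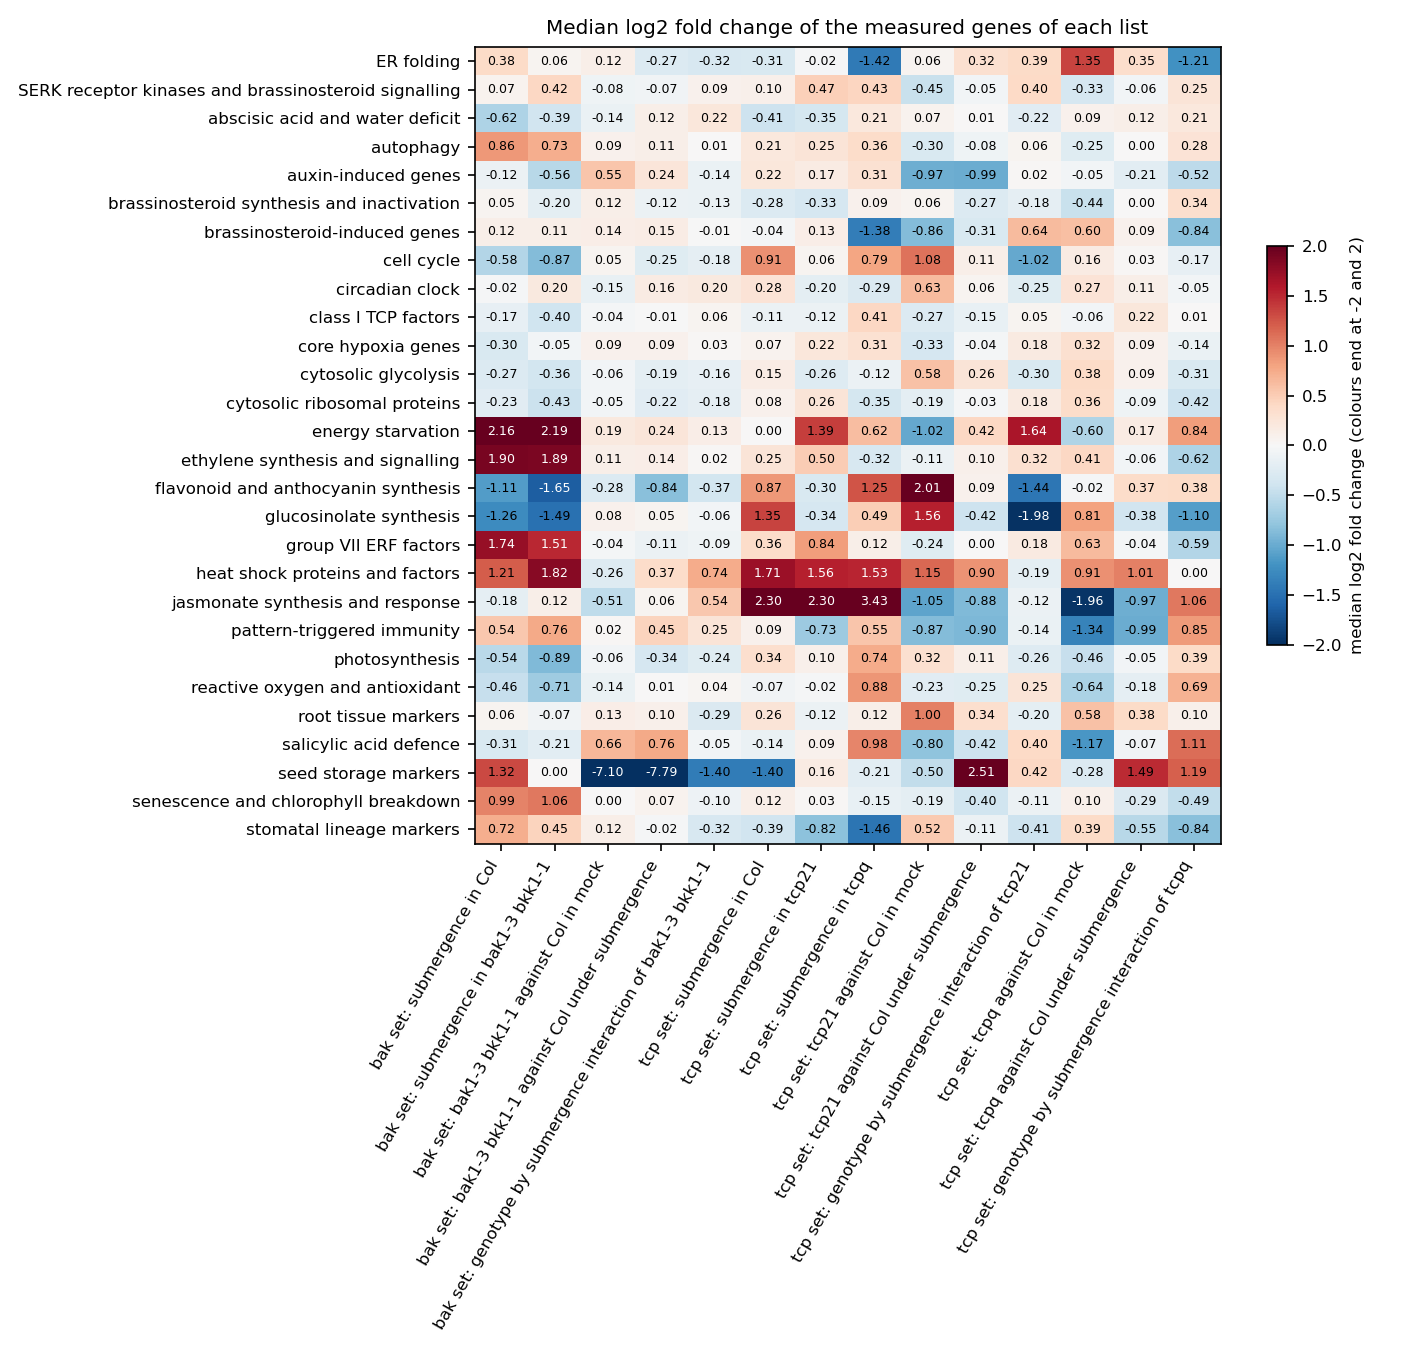
Median log2 fold change of each of the 28 gene lists (vertical) in each of the 14 comparisons (horizontal), coloured by the median. The medians of the seed storage list rest on genes with no counts in some groups and are no bound on a change.

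**Figure D5:**
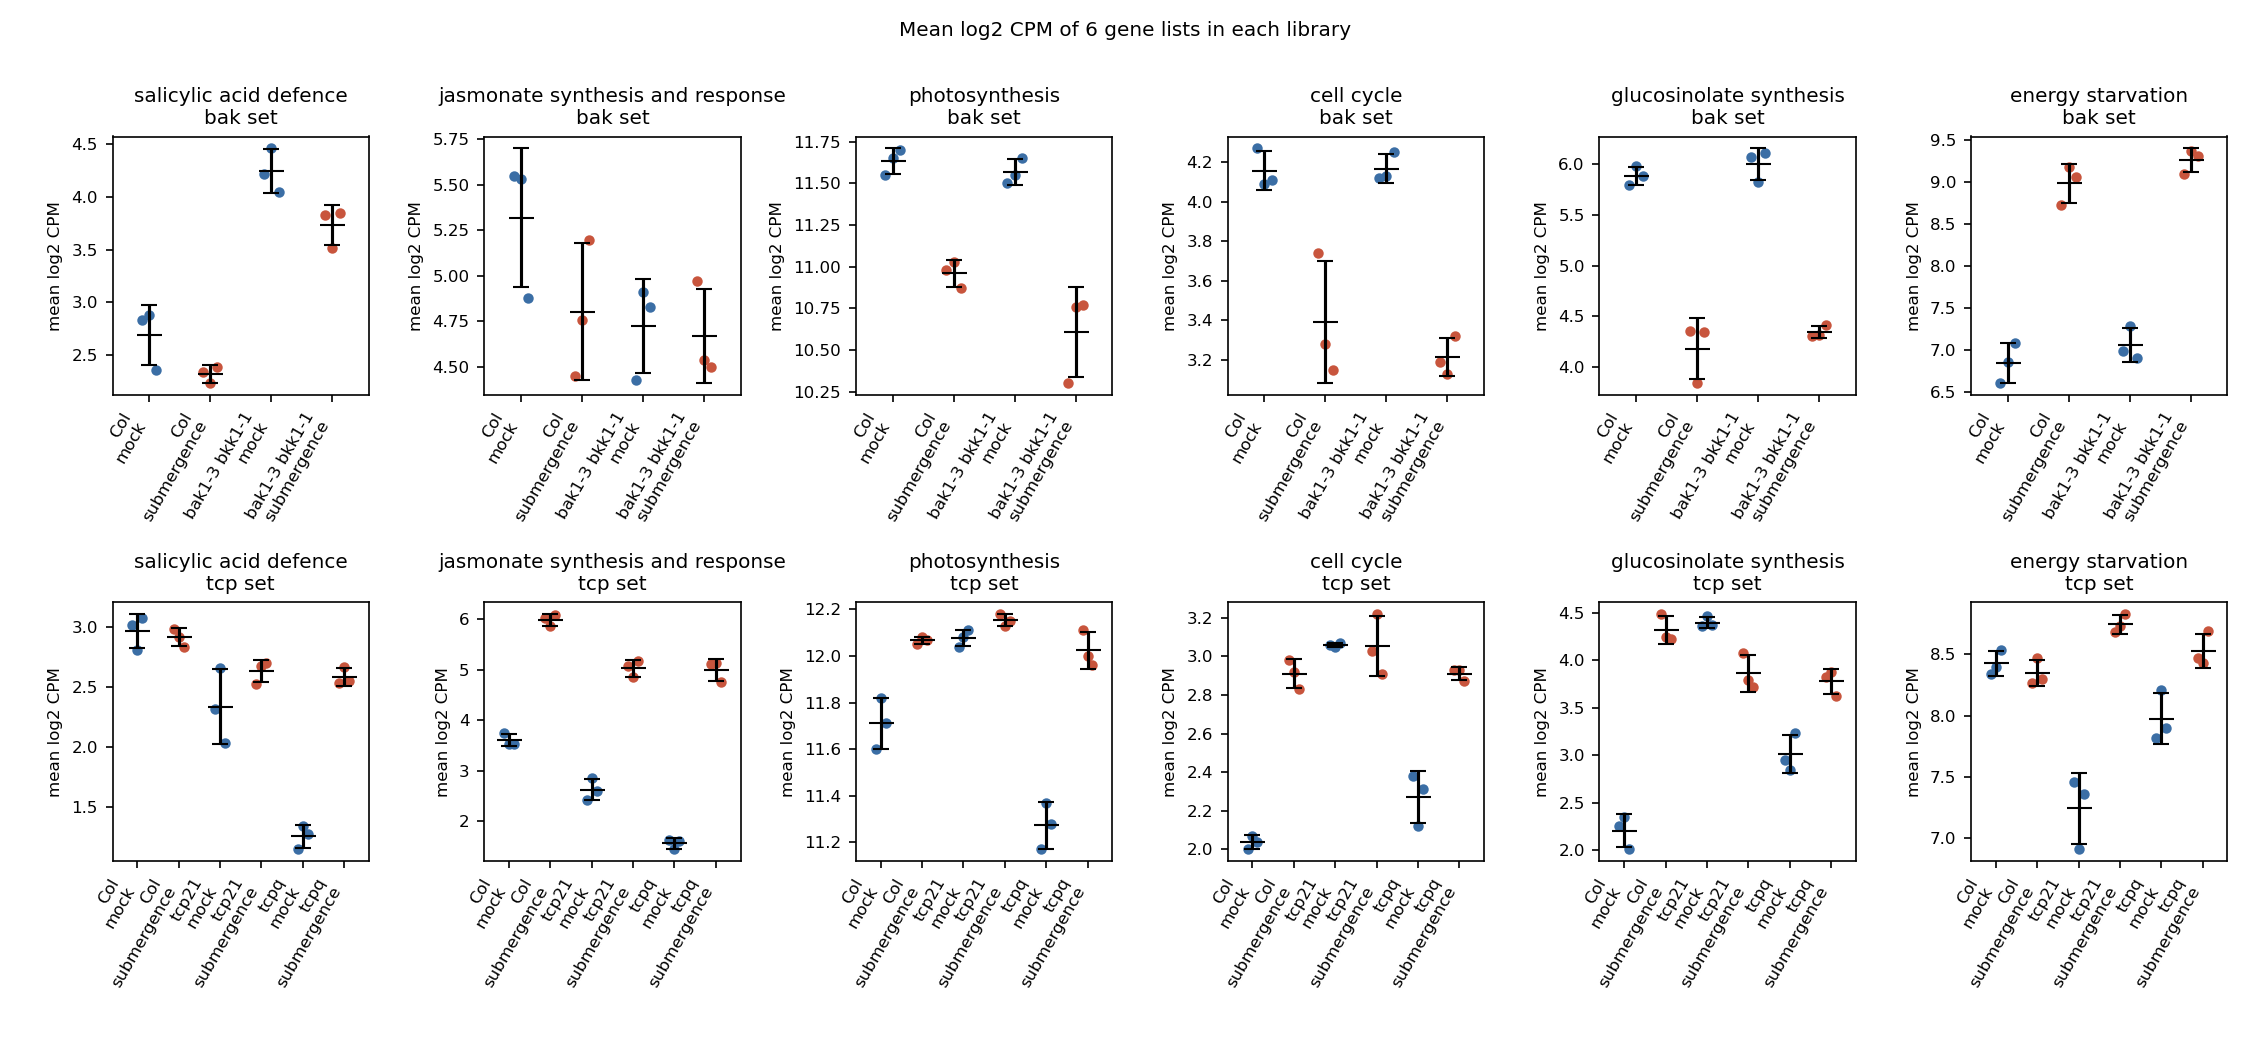
Mean log2 CPM of 6 gene lists per library by group, where points are libraries and the bar with its error is the mean ± SD of n = 3. The jasmonate list lay at 3.54 to 3.75 in Col mock libraries of the tcp set and at 5.86 to 6.08 in its Col submergence libraries.

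The Col responses of both sets were compared to see how far the wild type behaved alike. Of 5728 genes called in both, 3401 (59.4%) went the same way and 2327 opposite ways. Both rose for 1938 genes, with 1440 expected if calls were independent, and both fell for 1463, with 1170 expected. The Pearson r across genes was 0.134, where genes are not independent replicates. Glucosinolate genes show the contrast, with CYP83A1 at -2.43 ± 0.15 in the bak set and 3.92 ± 0.42 in the tcp set. No gene was tested for a difference between the sets, which share no library and were fitted apart.

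Mutants were compared with each other through the genes called in both. In mock, tcp21 and tcpq shared 4197 of 5806 genes (72.3%) in direction, with 2006 higher and 2191 lower in both against 1290 and 1070 expected, r of 0.354 across genes and a covariance of 0.288. Under submergence they shared 2011 of 2058 (97.7%), with 936 higher and 1075 lower against 216 and 247 expected, r of 0.58 and a covariance of 0.15. Both comparisons use the same Col libraries. Simulated unchanged mutants with shared Col libraries gave r of 0.511 in mock and 0.491 under submergence, with covariances of 0.0284 and 0.0219. In any of these draws at most 1 gene in mock and 0 genes under submergence were called in both in the same direction. The simulated r arises from noise alone, so it is no measure for the observed r. The draws also leave out any systematic shift of the shared Col libraries, which would enter both comparisons. They therefore do not show that the shared genes reflect the mutants. Jasmonate genes are among the shared falls, such as TAT3 with -4.50 ± 0.35 in tcp21 and -3.09 ± 0.29 in tcpq. Of genes changed in bak1-3 bkk1-1 under submergence, 25 were higher in tcp21 too (15 expected, Fisher's exact p = 0.00829) and 27 lower (21.1 expected, p = 0.156). With tcpq the numbers were 18 (10.7 expected, p = 0.0239) and 22 (11.6 expected, p = 0.00324), all two-sided Fisher's exact tests that treat genes as independent. With tcp21, 43 genes were called in opposite directions against 52 sharing a direction, and with tcpq 41 against 40. Of the 43, 30 were higher in bak1-3 bkk1-1 and lower in tcp21 (18 expected, Fisher's exact p = 0.00471) and 13 the other way round (17.3 expected, Fisher's exact p = 0.304). Of the 41, 23 were higher in bak1-3 bkk1-1 and lower in tcpq (10.1 expected, Fisher's exact p = 0.000172) and 18 the other way round (12.3 expected, Fisher's exact p = 0.098). Genes higher in bak1-3 bkk1-1 and lower in the other mutant exceeded the expected number as those higher in both did, so the overlaps give no common direction. The counts sharing a direction became 126 with tcp21 and 118 with tcpq under DESeq2, and 8 and 4 for calls of at least 2-fold. Across all genes r was 0.004 with tcp21 and -0.022 with tcpq. Between the interactions of bak1-3 bkk1-1 and tcp21, 0 genes were higher in both (0.297 expected) and 3 lower (1.31 expected, Fisher's exact p = 0.13). Between those of bak1-3 bkk1-1 and tcpq, 2 were higher (0.349 expected, Fisher's exact p = 0.0304) and 3 lower (1.39 expected, Fisher's exact p = 0.148), while 4 were lower in bak1-3 bkk1-1 and higher in tcpq (1.39 expected, Fisher's exact p = 0.0356).

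A score in log2 units on genes called in Col of the other set measured how far libraries moved along that response. It does not measure how much changed in total, since the score rose least in tcpq, which had the most called genes of the tcp set, 13029. In the bak set the score rose by 0.261 ± 0.079 (SD) in Col and 0.267 ± 0.059 in bak1-3 bkk1-1, a difference of 0.006 (exact permutation p = 0.91). In the tcp set it rose by 0.226 ± 0.021 in Col, 0.546 ± 0.076 in tcp21 and 0.102 ± 0.056 in tcpq. The difference from Col was 0.32 for tcp21 (exact permutation p = 0.03) and -0.125 for tcpq (exact permutation p = 0.015). With the median of log2 CPM the tcpq difference was -0.055 and lost its call (exact permutation p = 0.085). The tcp21 difference lost its call without the first Col submergence library, at 0.313. Mock levels set this apart, since the score in mock was -0.014 ± 0.075 in tcp21 and 0.298 ± 0.008 in Col, against 0.532 ± 0.007 and 0.525 ± 0.019 under submergence.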

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

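All tests in this part that weigh an explanation, and the regroupings of libraries, were chosen after the results had been seen.

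Groups differed in how genes responded to submergence. The interaction of bak1-3 bkk1-1 had 10 called genes, with fitted values of 1.36 for AT2G39710, 0.81 for OCT3, -3.24 for AT5G25260, -2.05 for CYP86B1, -2.05 for AT5G42530, -2 for XTH20, -1.81 for AT2G22510 and -1.27 for AT2G41090. With a replicate block AT2G39710, CYP86B1 and AT5G42530 also lost their calls (edgeR adjusted p = 0.0801, 0.0566 and 0.0801). With RLE size factors the same genes and AT5G25260 lost them (edgeR adjusted p = 0.0508 for each). Regrouping did not exclude chance for the 10 calls, with 5 of 100 splits as large, the real one included. The highest other stood at 26. Of the 4 other splits as large, 3 keep the real genotype groups in mock and 1 those under submergence, so they carry differences between the genotypes. The interaction of tcp21 had 6314 called genes. Its largest fitted values were 9.63 for ddf2, 7.36 for DDF1, 4.65 for SRO5, 4.27 for JAZ8, 3.86 for AT1G50040 and 3.76 for AT1G77640, and on the negative side -11.4 for IRT1, -8.65 for CYP79F1, -7.04 for FMO GS-OX3, -6.71 for MYB29, -6.43 for AK3 and -5.98 for CYP83A1. BKK1 had 0.74. The interaction of tcpq had 7023 called genes. Its largest fitted values were 9.97 for ddf2, 9.16 for DDF1, 7.91 for AT4G27654, 7.34 for JAZ8, 6.99 for AT4G17470 and 6.16 for RAS1, and -6.13 for AT1G49570, -5.6 for AT2G41810, -4.88 for AT1G47400, -4.80 for AT5G50335, -4.26 for XTH20 and -4.21 for EXPA17. BKK1 had 0.96 and TCP21 1.71. Where a group has few or no counts, as for ddf2 and IRT1, the fitted value depends on the prior count and is no bound. Regrouping exchanged genotypes within each treatment, so it tests for any difference between genotypes and not for an interaction alone. For tcp21, 3 of 100 splits were as large, the real one included, with the highest other at 6566. For tcpq, 1 of 100 was as large, the real one at 7023, with the highest other close to it at 6966. Genotype labels without any effect are excluded at a share under 0.05, but chance in the interaction is not. The 2 other tcp21 splits as large keep the real mock groups, so many of the tcp21 calls may rest on the mock libraries.

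Comparisons of 2 groups allow only 10 splits, too few for a share under 0.05. In each of them the real grouping alone reached its count, which makes 1 of 10. The real counts and highest other counts were 10441 and 0 for submergence in Col of the bak set, 11072 and 0 in bak1-3 bkk1-1, 195 and 1 for bak1-3 bkk1-1 against Col in mock and 285 and 0 under submergence. In the tcp set they were 10287 and 0 for submergence in Col, 10172 and 1 in tcp21 and 13029 and 0 in tcpq. For tcp21 against Col they were 9668 and 1 in mock and 5505 and 0 under submergence, and for tcpq 9958 and 0 and 3440 and 0. No single library was tested for its distance from its group of 3.

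The wide differences between genotypes in mock libraries of the tcp set have several candidate explanations. Harvest at another time of day remains possible, because the clock list's median absolute fold change of 0.9 in tcp21 and 0.74 in tcpq lay at the 100 and 99.9 percentiles of 10000 random lists of like expression, against 76 and 61.5 under submergence. Handling of the seedlings before harvest remains possible too, because an added list of touch and wound genes had medians of -1.63 in tcp21 and -2.23 in tcpq, for example TCH4 (AT5G57560) at -2.65 ± 0.29 in tcp21. The list had unadjusted camera p = 1.61e-06 in tcp21 and p = 1.73e-06 in tcpq, and p = 0.147 and p = 0.148 with an estimated correlation. Organelle transcripts or RNA quality stay open. The 9958 calls of tcpq against 9668 of tcp21 did not follow the chloroplast share, which was 0.0382 to 0.0655% in tcpq mock libraries and 0.22 to 0.564% in those of tcp21, but all tcpq mock libraries lay above the 0.029 to 0.0365% of Col mock libraries, so this count excludes nothing. RNA quality itself was not measured. An effect of genotype stays open, because TCP21 itself binds a clock gene promoter and each genotype's mock seedlings may have been grown or harvested together.

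Seed storage transcripts in 4 Col libraries of the bak set, the second in mock and all 3 under submergence, were weighed next. Seed tissue in those libraries remains open. Of the other genes raised at least 4-fold in the second Col mock library, 10 of 43 (23.3%) were raised in every Col submergence library. Among all genes 20 (0.0968%) were, these 10 included. The extraction text names germinating seeds beside seedlings, without saying for which libraries. In mock the 10 seed storage genes summed to 1.63, 296 and 1.39 CPM in Col. This spread within Col argues against genotype as the sole cause in mock. Of the 10 genes, 3 were higher in all Col than in all mutant libraries, while chance gives that order in a share of 0.05. Their lowest Col values were 0.044, 0.0841 and 0.168 CPM against 0 in the mutant, too near the floor for this count to decide. Of the 151 genes called lower in bak1-3 bkk1-1 under submergence, 5 were among the genes raised at least 4-fold in the second Col mock library. That set comes from 1 library, so it puts no upper limit on the genes that seed tissue could account for.

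The submergence response of Col was unlike in both sets, which share no library. In 8 of 28 lists all Col submergence libraries lay on opposite sides of all Col mock libraries in the 2 sets, a difference that was not tested for the lists together, and the mean log2 changes in the bak and tcp sets were -0.21 and 0.22 for core hypoxia genes, -0.67 and 0.36 for photosynthesis, -0.2 and 0.27 for the clock, -0.77 and 0.87 for the cell cycle, -0.98 and 0.73 for flavonoids, -1.7 and 2.1 for glucosinolates, 1.02 and -0.49 for ER folding and 0.61 and -0.28 for stomatal lineage markers. The core hypoxia means show no reversal of that list as a whole. Its genes rose and fell in each set, its list test passed in neither, and PDC2 and ADH1 rose in both. Clock genes too went both ways in Col of the bak set. Exchanged Col labels in the tcp set are excluded, since its Col response correlated across genes with those of tcp21 and tcpq at r = 0.55 and 0.617. Sets harvested at different times of day remain possible, because the clock list's median absolute difference of 0.84, against 0.53 in random lists, lay at percentile 97. Submergence times that differ between the sets could also make the Col responses unlike and have no test here.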

How the results depend on the processing

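The alternatives were chosen before the data were examined, apart from 2 added after, which left out organelle genes or the 53 genes at least 4-fold higher in the second Col mock library. The first moved the median fold change of all genes by at most 0.004 and so tests little. The second kept all 5 comparisons it was applied to, with 280 calls for bak1-3 bkk1-1 under submergence without the seed-like genes. Only 5 of the 151 genes called lower there were in the set left out, which comes from 1 library. The second alternative therefore tests little for seed tissue as well. A looser filter, a stricter filter and a fit of the compared groups alone left all 14 counts within 1.5-fold. DESeq2 kept 11 of 14. It gave 322 calls for bak1-3 bkk1-1 against Col in mock and 668 under submergence, with 190 and 279 shared. For the bak1-3 bkk1-1 interaction it gave 95, 34 higher and 61 lower, with all 10 shared, and there RLE size factors gave 4, all shared, and a replicate block 5, with 3 shared. DESeq2 also had 19.1% false calls in simulated counts of the bak set, but the cause of these differences was not tested. Overlaps moved with it, to 32 genes for the interactions of bak1-3 bkk1-1 and tcp21, 27 for bak1-3 bkk1-1 and tcpq, and under submergence to 126 with tcp21 and 118 with tcpq, and the cause was not tested. Calls of at least 2-fold lowered overlaps because fewer genes count, to 610 for both Col responses, 1 for the interactions of bak1-3 bkk1-1 and tcpq, 8 and 4 for bak1-3 bkk1-1 with tcp21 and tcpq under submergence, and 954 in mock and 219 under submergence for tcp21 with tcpq. The difference of tcpq in the response score became -0.055 with the median of log2 CPM (exact permutation p = 0.085), and the cause was not tested. Under DESeq2 the balance of calls reversed in 3 lists. Under submergence these were cytosolic glycolysis in bak1-3 bkk1-1 (1 higher, 2 lower) and brassinosteroid synthesis in tcp21 (3 higher, 2 lower). In the tcp21 interaction senescence reversed (3 higher, 2 lower). The cause was not tested. Of the 28 lists chosen before, only ethylene kept a camera call with an estimated correlation, in both genotypes of the bak set. Of 204 values of named genes, DESeq2 kept 200, RLE size factors 197 and the block 198. Leaving out single libraries kept 1369 of 1470 such values. Counts ranged from 9233 to 10266 for submergence in Col of the bak set and from 9921 to 10218 in bak1-3 bkk1-1. They ranged from 124 to 226 for bak1-3 bkk1-1 in mock, 184 to 314 under submergence and 0 to 11 for its interaction. In the tcp set they ranged from 8966 to 9909 for submergence in Col, 9016 to 9806 in tcp21 and 12083 to 12423 in tcpq. For tcp21 they ranged from 8344 to 9170 in mock, 3441 to 5599 under submergence and 5448 to 6378 for the interaction, and for tcpq from 8821 to 9363, 2329 to 3365 and 6180 to 6904. Response score differences ranged from -0.027 to 0.04 for bak1-3 bkk1-1, 0.276 to 0.343 for tcp21, with 1 omission past the threshold, and -0.148 to -0.103 for tcpq. Scaling choices moved the median fold change of all genes by at most 0.032. Recovery of 1.5-fold interactions was simulated at the depth, spread and number of libraries of these sets together, with few genes changed. It reached 7 of 100 in the bak set, 20 with tcp21 and 34 with tcpq.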

Other observations

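The test and both added gene lists in this part were chosen after the results had been seen.

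A common response ran through all 5 comparisons of submergence with mock. AT2G38240, ABR1, the cold and drought genes KIN1 and RD29A, and CYP94C1 rose in each. The fold changes of ABR1 were 5.84, 6.44, 5.06, 6.87 and 6.77 in Col and bak1-3 bkk1-1 of the bak set and in Col, tcp21 and tcpq of the tcp set. In the same order KIN1 had 4.17, 4.29, 4.15, 3.85 and 6.35, and RD29A 3.14, 3.38, 4.8, 3.67 and 3.97. The ethylene synthesis gene ACS8 rose in all 5 as well, by 3.37, 3.89, 3.21, 4.28 and 4.19. EXPA8 fell in each, with -3.23, -3.61, -3.11, -4.41 and -5.12. Of 20069 genes tested in both sets, 1084 rose and 646 fell in all 5, against 31.3 and 25.5 expected if calls were independent. Groups that share libraries or a genotype are not independent, and the expected numbers leave this out.

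Iron deficiency genes were raised in mock seedlings of bak1-3 bkk1-1. The transcription factor genes BHLH100 (AT2G41240), bHLH38 (AT3G56970) and bHLH39 (AT3G56980) were higher by 2.72 ± 0.29, 2.31 ± 0.28 and 2.07 ± 0.32. Of the added list 7 of 19 measured genes were higher and 0 lower, with an unadjusted camera p = 4.47e-11, and p = 0.0038 with an estimated correlation. In the interaction 0 genes of the list were called, with a median of -0.91 and camera p = 1.16e-09, and p = 0.00587 with an estimated correlation. In mock tcp21, 13 of 18 were higher and 2 lower, such as FRO2 (AT1G01580) by 2.60 ± 0.42 and NAS4 (AT1G56430) by 2.05 ± 0.24, with camera p = 0.000856, and p = 0.0832 with an estimated correlation. In mock tcpq 4 were higher and 2 lower, with a median of 0.01. The list test there gave camera p = 0.707, and p = 0.835 with an estimated correlation. The touch and wound list had 1 of 20 measured genes rising and 14 falling with submergence in Col of the bak set, with a median of -1.93 and camera p = 5.7e-06, and p = 0.137 with an estimated correlation. In tcp21 mock it had 1 higher and 14 lower, and in tcpq mock 0 higher and 12 lower. Unadjusted camera p was 1.61e-06 and 1.73e-06 there, and 0.147 and 0.148 with an estimated correlation. With submergence in the tcp set the list went the other way, with medians of 0.5 in Col, 1.35 in tcp21 and 2.4 in tcpq, and 8 rose and 0 fell in Col, 13 and 1 in tcp21 and 16 and 0 in tcpq. Unadjusted camera p was 0.0888, 1.03e-06 and 1.6e-05 in that order, and 0.593, 0.141 and 0.189 with an estimated correlation.

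IRT1, NAS3 and FRO5 were among the largest changes of the tcp set, and a wider iron deficiency response is a candidate explanation that stays open. The list's medians were 0.69 for submergence in Col and 1.33 for tcp21 in mock. With submergence in Col 7 genes rose and 3 fell. The list test did not pass there, with unadjusted camera p = 0.112, and p = 0.386 with an estimated correlation.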
